A study of Mus musculus with 4 samples.

How the data were processed

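RNA from the cervical spinal cord of male NC/Nga mice, 9 weeks old, was measured on 4 Illumina BeadChip arrays. NC/Nga is an inbred strain that develops a skin disease resembling human atopic dermatitis when kept in a conventional room and stays free of it in specific-pathogen-free (SPF) housing. Per the labels, 2 arrays came from SPF mice with a normal phenotype and 2 from conventionally housed mice with the dermatitis phenotype. The group and the replicate number of each array were taken from its title. Per the labels' protocols, total RNA was extracted with TRIsure, checked on an Experion system, and turned into biotinylated cRNA with an Illumina TotalPrep kit.

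The deposited bead signals are intensity values on a linear scale, 1 per probe and array, and per the file headers they had not been normalized. Beside each signal stands a detection p-value, per the file headers, which compares the probe with the negative-control beads of its array. The authors' own value table, used only as an alternative, holds intensity values that they had normalized. Its columns have medians of 216.5, 216.5, 216.5 and 216.6, a lowest value of 182.2 and a highest of 34269.1 in each column. Within each column the probes rank as in the signals of the same array (rank correlation 1, against at most 0.923 with any other array). The scale is linear and no centring of genes was applied, but the low values are compressed by a transformation that stays unknown. The submitters' processing notes name lumi. Its version and settings, the scanner software and the genome build are not given in the sources used here.

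Genes were named through the annotation of the array platform. Of 45281 probes, 34885 carry 1 gene symbol, 18 carry several and 10378 have none in that annotation. The gene number of 34807 probes was found in a RefSeq gene table of assembly GRCm38.p6, which was used for names only and changed 0 symbols. No coordinates are given, since no source names a build for the array.

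Signals were background-corrected and quantile normalized with neqc of limma (version 3.58.1, R 4.3.3), which adds an offset of 16 and takes log2. The negative-control mean and variance were inferred from the detection p-values. A probe was kept where its detection p was under 0.05 on at least 2 of the 4 arrays, which left 21065 probes. A gene with several kept probes was represented by the probe with the highest mean, and an unnamed probe by itself, which gave 14634 features (11476 named genes and 3158 unnamed probes). Of 4389 genes with several kept probes, 2012 had probes that differed in sign, so a value belongs to its probe. Where a probe was not above background on any array of a group, the fold is a lower bound. That bound sets the mean of the brighter group against the mean, over the dim group's arrays, of the lowest value among probes above background or the probe's own value, whichever is higher.

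The groups were compared with limma's moderated linear model (lmFit, and eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Differences are conventional minus SPF on the log2 scale, and errors are the model's standard errors. Gene lists were compared with camera at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. The design, the 36 lists, the naming rule and all alternatives but 2 were chosen before the data were examined. The rule named up to 12 genes per direction past the threshold, filled up with the smallest unadjusted p among genes whose groups do not overlap, then the 3 members of each list with the largest absolute difference, and Gfap, Lcn2, Stat3, Grp, Grpr, Npr1, Aif1 and Fos. Genes chosen after their values were seen are marked as such.

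The fit was tested on simulated data with the means and spreads of these arrays (14634 features, 20 simulations). It called 90.1% of genes changed by 2 log2 units, 26.9% of those changed by 1 and 0.821% of those changed by 0.5, and 0.0357% of unchanged genes. Each simulation changed 66, 67 and 67 genes by these amounts together, which eases the adjustment. A gene of median spread changed alone would need a difference of 2.67 log2 units to pass. With lists shifted by 0.5 log2 units, camera called 100% of shifted and 0.2% of other lists at the preset correlation, and 0% of either with an estimated correlation. The list simulation drew genes independently, so it says nothing about error rates where the members of a list vary together between arrays.

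Alternatives covered background correction, 2 other normalizations, the authors' table, 2 other filters on dim probes, the mean of a gene's probes, 3 variance models, the replicate number as a block, other thresholds, other set tests, and each array left out in turn. The files give no slide or scan batch. Nothing in the labels says whether the 2 replicates of a group are separate animals or pools, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value.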

Results

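The cervical spinal cord, which receives sensory input from the skin of the neck and forelimbs, was profiled in NC/Nga mice with and without an atopic dermatitis phenotype. The comparison asks which transcripts differ in the cord of the affected, conventionally housed mice. There were 2 arrays per group. Probes above background numbered 20493 and 20334 on the SPF arrays (45.3% and 44.9% of the array) and 20689 and 20960 on the conventional arrays (45.7% and 46.3%). Median signals before normalization were 114.1 and 119.4 against 113.6 and 116.4. All errors below are standard errors of the model with n = 2 arrays per group, unless named otherwise.

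Of 14634 features, 0 passed the threshold in limma's test, 443 had an unadjusted p under 0.05 (192 higher and 251 lower in conventional mice), and 731.7 would be expected at that p by chance. The lowest adjusted p was 0.476, shared by 2 genes, and the rest were at 1. Those 2 genes were Hspa1a, a heat-inducible chaperone, with a log2 difference of 1.83 ± 0.22 (3.57-fold higher, detected on 1 of 2 SPF arrays), and Opalin, a membrane protein of myelinating oligodendrocytes, at -0.92 ± 0.11 (1.90-fold lower). The groups did not overlap in 15.6% of features with conventional above SPF and in 15.1% with conventional below. Chance gives 16.7% for each. In 35 features the means also differed by at least 2-fold (12 higher, 23 lower).

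The genes with the smallest p whose groups do not overlap are given here as values, since none passed the test over all genes. Higher in conventional cord were Lcn2 (2.30 ± 0.50), which encodes the secreted siderophore-binding protein lipocalin-2, Nms (1.54 ± 0.30), which encodes neuromedin S, and the neuropeptide precursor genes Vgf (1.32 ± 0.20) and Cartpt (1.27 ± 0.25). The others on this side were Pglyrp1, a peptidoglycan recognition protein (0.99 ± 0.15), Depp1 (0.94 ± 0.21, detected on 1 of 2 SPF arrays), the cell cycle inhibitor Cdkn1a (0.76 ± 0.16), Ly6c1 (0.75 ± 0.17), Fam107a (0.71 ± 0.15), the transcriptional repressor Bcl6 (0.56 ± 0.13) and Stk32a (0.53 ± 0.12). A further probe of Pglyrp1 gave 0.19 and one of Stk32a 0.04. Lcn2 stood at 9.46 and 7.71 log2 units on the conventional arrays and at 6.29 and 6.28 on the SPF arrays. Without conventional replicate 2 its difference was 3.17, and over the 4 fits that left out 1 array it ranged from 1.43 to 3.17.

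Lower in conventional cord were Erdr1 (-1.63 ± 0.28; a further probe gave -0.61), the beta- and alpha-globin genes Hbb-bt (-1.09 ± 0.23) and Hba-a1 (-1.21 ± 0.27), the troponin gene Tnnt1 (-1.03 ± 0.22), Sp7 (-0.90 ± 0.19), Sgk2 (-0.81 ± 0.19), Ppp1r14a (-0.55 ± 0.13) and Agpat2 (-1.02 ± 0.25, detected on 1 of 2 conventional arrays; a further probe gave -0.06). Ccn5, the organic anion transporter gene Slc22a8 and Angptl7 were not above background on either conventional array, and were at least 2.33-fold, 1.97-fold and 1.76-fold lower there. Erdr1 differed by -2.08 without conventional replicate 2, within a range of -2.08 to -1.18 over the 4 fits that left out 1 array.

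**Figure D1:**
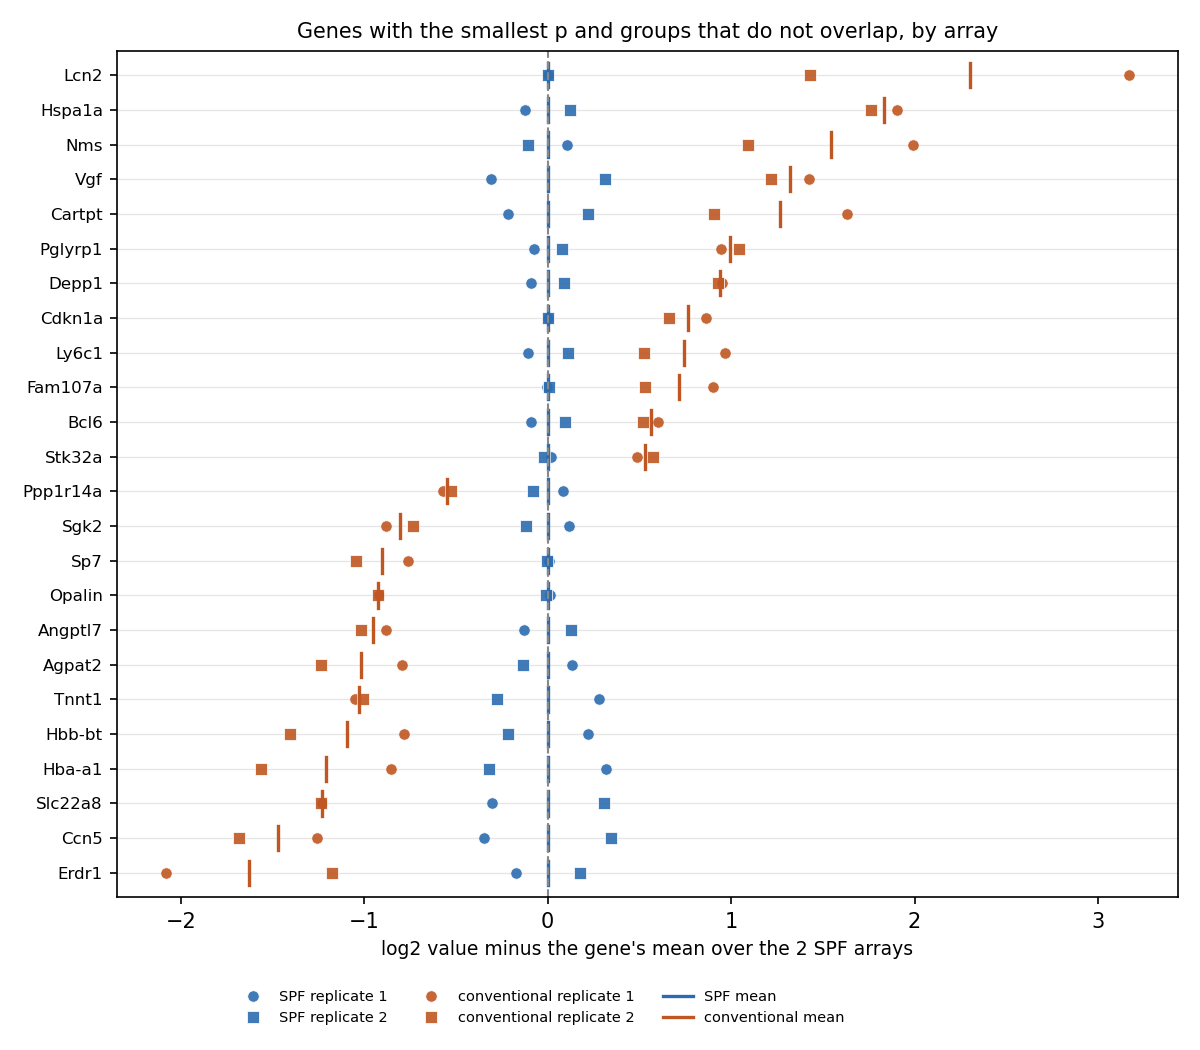
Log2 value of each named gene on each array minus the gene's mean over the 2 SPF arrays (x axis, log2 units); points are arrays, circles replicate 1 and squares replicate 2, and vertical bars are group means of 2 arrays. Conventional arrays lie on 1 side of the SPF arrays for every gene by the rule that chose them, Lcn2 has the widest gap between the conventional arrays (3.17 and 1.43 above the SPF mean), and Opalin has its 2 arrays of each group nearly on top of each other.

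Among the genes fixed for this model of itch, Gfap, the astrocyte filament gene, differed by 0.16 ± 0.32, Stat3 by -0.02 ± 0.14 (its other probes reached 0.31), the itch peptide gene Grp by 0.29 ± 0.41, its receptor gene Grpr by -0.22 ± 0.24, the microglial gene Aif1 by -0.29 ± 0.21 (a further probe gave 0.09) and Fos by 0.39 ± 0.18. None passed the test. With 1 array left out, Aif1 ranged from -0.47 (without SPF replicate 2) to -0.11 (without SPF replicate 1) and Fos from 0.20 (without conventional replicate 2) to 0.59 (without conventional replicate 1). The 95% intervals reached from -0.60 to 0.93 for Gfap and from -0.68 to 1.26 for Grp, and differences within these ranges are not excluded at this number of arrays. Npr1, a natriuretic peptide receptor gene, was detected on 1 array and not tested.

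Of 36 gene lists, 32 had at least 5 tested members, and 14 passed camera at the preset correlation, 8 higher and 6 lower in conventional cord. With an estimated correlation 0 passed (lowest adjusted p = 0.814), and with fry 0 passed in either form (lowest adjusted p = 0.871 for a shift in 1 direction and 0.230 for change in either direction). In the simulation camera with an estimated correlation called 0% of lists shifted by 0.5 log2 units. Its lack of calls, here and for each list below, therefore does not tell a list shifted by that amount from an unshifted one. Larger shifts were not simulated, and neither was fry, whose lack of calls is a limit on all 14 lists. The estimated correlation between genes of a list was above 0.1 in 12 of the 14 lists, against the preset 0.01, so the preset p-values understate how much list members vary together between these arrays. Camera at the preset correlation also passed 8 of the 14 lists when the arrays were split by replicate number instead of group. Over all genes 0 list members passed. Adjusted over the list alone, 14 memberships passed in 7 lists, and these were 12 genes. That adjustment does not cover the search over 32 lists, so a gene said below to pass it is not a call over all genes.

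Chaperone and protein folding genes rose as a set in conventional cord: 19 of 21 were higher, 13 of them on both conventional arrays above both SPF arrays, with a mean difference of 0.35 (camera, adjusted p = 7.09e-10; adjusted p = 0.814 with an estimated correlation). Adjusted over the list alone, Hspa1a passed (adjusted p = 0.00137), as did the HSP40 co-chaperone gene Dnajb1 (0.44 ± 0.11), the endoplasmic reticulum chaperone gene Calr (0.71 ± 0.18) and Creld2 (0.73 ± 0.19), the last 3 at an adjusted p of 0.0376. Hspa1b, a near-identical copy of Hspa1a, differed by 0.04 ± 0.23 and was detected on 1 of 2 SPF arrays. Probes for such copies can share targets, so the assignment to Hspa1a is uncertain.

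Targets of the glucocorticoid receptor also rose as a set, with 15 of 20 higher, 10 of them with no overlap between the groups, and a mean difference of 0.43 (adjusted p = 1.65e-07; adjusted p = 0.814 with an estimated correlation). Adjusted over the list alone, Cdkn1a, Lcn2 and the lipid droplet gene Plin4 (1.20 ± 0.29; 0.75 without SPF replicate 2) passed. The mean was 0.23 without conventional replicate 1. Immediate-early genes, which neurons switch on within minutes of activity, rose as a set with 12 of 14 higher and a mean of 0.29 (adjusted p = 8.39e-05; adjusted p = 0.814 with an estimated correlation). Fosb differed by 0.91 ± 0.22, Egr3 by 0.74 ± 0.23 (a further probe gave -0.06) and Dusp1, which stands in both lists, by 0.45 ± 0.16. Adjusted over the list alone, 0 immediate-early genes passed. The heat shock, glucocorticoid and immediate-early lists kept their call without any 1 array. On the same arrays the lists of skeletal muscle, meningeal and red blood cell genes were lower in conventional cord.

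Genes of cholinergic and motor neurons rose as a set: 11 of 11 were higher, 9 of them with no overlap between the groups, with a mean of 0.51 (adjusted p = 3.01e-08; adjusted p = 0.814 with an estimated correlation). The choline transporter gene Slc5a7 differed by 0.71 ± 0.25, the vesicular acetylcholine transporter gene Slc18a3 by 0.70 ± 0.24, Calcb, which encodes a calcitonin gene-related peptide, by 0.76 ± 0.27, and Chat, which encodes the acetylcholine-synthesizing enzyme, by 0.45 ± 0.24. With 1 array left out, Chat ranged from 0.12 to 0.78 and Slc5a7 from 0.37 to 1.05 (lowest without SPF replicate 1, highest without SPF replicate 2). Slc18a3 ranged from 0.39 to 1.02 and Calcb from 0.44 to 1.08 (lowest without conventional replicate 2, highest without conventional replicate 1). Adjusted over the list alone, 0 passed. Of the 4 tested markers of dorsal root ganglion neurons, Isl1 (0.70 ± 0.31) and Prph (0.58 ± 0.21) also stand in this list. Ret (0.48 ± 0.18) likewise had both conventional arrays above both SPF arrays, and Th (0.19 ± 0.38) overlapped. General neuronal genes rose by a mean of 0.12, with 8 of 10 higher (adjusted p = 0.0122; adjusted p = 0.814 with an estimated correlation), among them the neurofilament gene Nefm (0.40 ± 0.10) and Gap43 (0.27 ± 0.14). That call was lost without SPF replicate 1 (mean 0.12, adjusted p = 0.0572) and without conventional replicate 2 (mean 0.08, adjusted p = 0.282), and under 2 of 10 other processing choices (highest adjusted p = 0.107). Genes of oxidative phosphorylation rose by a mean of 0.07, with 15 of 20 higher (adjusted p = 0.0271; adjusted p = 0.864 with an estimated correlation), among them Uqcrh (0.22 ± 0.10) and Ndufa2 (0.18 ± 0.11), and lost the call without SPF replicate 1 (mean -0.01, adjusted p = 0.893) and without conventional replicate 2 (mean 0.03, adjusted p = 0.503), and under 3 of 10 other processing choices (highest adjusted p = 0.137). The mean was 0.16 without SPF replicate 2 and 0.11 without conventional replicate 1.

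Peptides and receptors of itch and pain circuits in the dorsal horn did not pass as a set, with 14 of 23 higher and a mean of 0.09 (adjusted p = 0.374). Tac1, which encodes substance P, differed by 0.99 ± 0.40, Gal, which encodes galanin, by 0.74 ± 0.46, and Pdyn, which encodes prodynorphin, by 0.59 ± 0.44, and in all 3 the groups overlapped. Tac1 ranged from 0.40 without conventional replicate 1 to 1.58 without conventional replicate 2. This list depended on single arrays: its mean was 0.35 without conventional replicate 2, 0.27 without SPF replicate 1 and -0.17 without conventional replicate 1. It passed camera at the preset correlation with probes of a detection p under 0.01 on all 4 arrays (mean 0.17, adjusted p = 0.0479). Under the other processing choices its adjusted p reached up to 0.512. Excitatory (4 of 10 higher, mean -0.08, adjusted p = 0.796) and inhibitory neuron genes (3 of 6 higher, mean 0.07, adjusted p = 0.714) did not pass.

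Astrocyte lists did not pass. Pan-reactive astrocyte genes had 8 of 14 higher and a mean of 0.12 (adjusted p = 0.399), with Lcn2 as the member of largest difference, followed by Cp at -0.67 ± 0.64 and Aspg at -0.53 ± 0.56. Lcn2 passed when adjusted over the list alone. The pan-reactive mean was 0.55 without conventional replicate 2 and -0.31 without conventional replicate 1. A1-type reactive genes had 3 of 8 higher (mean -0.15, adjusted p = 0.624), with a mean of -0.45 without conventional replicate 1. Homeostatic astrocyte genes had 7 of 13 higher (mean -0.01, adjusted p = 0.796).

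Myelinating oligodendrocyte genes fell as a set, with 13 of 13 lower and a mean of -0.17 (adjusted p = 0.00811; adjusted p = 0.864 with an estimated correlation). Opalin had the largest difference of the list and passed adjusted over the list alone (adjusted p = 0.000809). Mog (-0.19 ± 0.22) and Aspa (-0.20 ± 0.25) did not, and without each list's member of largest difference, an alternative chosen after seeing the data, the list lost its call (mean -0.11, adjusted p = 0.108). The call was also lost without SPF replicate 1 (mean 0.01) and without conventional replicate 2 (mean -0.13), and without SPF replicate 2 the mean was -0.34. Oligodendrocyte precursor genes did not pass (5 of 11 higher, adjusted p = 0.796).

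Microglial genes fell as a set, with 12 of 17 lower and a mean of -0.17 (adjusted p = 0.0362; adjusted p = 0.864 with an estimated correlation), among them Tyrobp (-0.68 ± 0.31), Trem2 (-0.44 ± 0.27) and Gpr34 (-0.33 ± 0.22). The mean turned to 0.06 without SPF replicate 1 (adjusted p = 0.446) and to 0.06 without conventional replicate 2 (adjusted p = 0.503), and was -0.40 without either of the other arrays. The call was also lost under 4 of 10 other processing choices (highest adjusted p = 0.158). Genes of MHC class II presentation fell with 6 of 7 lower and a mean of -0.34 (adjusted p = 0.0101; adjusted p = 0.864 with an estimated correlation). The invariant chain gene Cd74 differed by -0.99 ± 0.27, H2-Eb1 by -0.56 ± 0.32 (detected on 1 of 2 conventional arrays) and H2-Ab1 by -0.31 ± 0.21 (a further probe gave 0.12). Without conventional replicate 2 that list lost its call (mean -0.16, adjusted p = 0.435), and without conventional replicate 1 its mean was -0.52. MHC class I presentation (10 of 11 lower, adjusted p = 0.139), interferon response (12 of 17 lower, adjusted p = 0.212), complement and acute phase (9 of 13 lower, adjusted p = 0.123) and type 2 and itch cytokine genes (6 of 10 lower, adjusted p = 0.718) did not pass. Without conventional replicate 1 the mean of complement and acute phase genes was -0.73, that of interferon response genes -0.26 and that of MHC class I genes -0.19. MHC class I genes passed camera at the preset correlation with probes of a detection p under 0.01 on all 4 arrays (mean -0.14, adjusted p = 0.0412). Under the other processing choices their adjusted p reached up to 0.435. Complement and acute phase genes had a mean of -0.27 without SPF replicate 2.

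Neutrophil genes rose as a set, with 11 of 11 higher and a mean of 0.58 (adjusted p = 0.00348; adjusted p = 0.864 with an estimated correlation), but the shift lay on conventional replicate 1. Without that array the mean was -0.21, and without conventional replicate 2 it was 1.37. The calprotectin genes S100a8 (0.77 ± 0.61) and S100a9 (0.72 ± 0.75) had overlapping groups, and adjusted over the list alone Lcn2 passed and no other member did. Red blood cell genes fell as a set, with 6 of 8 lower and a mean of -0.56 (adjusted p = 0.000382; adjusted p = 0.814 with an estimated correlation). Adjusted over the list alone, Hba-a1, Hbb-bt and Hbb-bs (-1.05 ± 0.27; -0.69 without conventional replicate 2) passed. These globin genes are near-identical within each family, so the split between Hbb-bt and Hbb-bs is uncertain. Without conventional replicate 2 the mean of the list was -0.25, without SPF replicate 1 -0.37 and without conventional replicate 1 -0.86. Endothelial genes rose with 8 of 13 higher and a mean of 0.15 (adjusted p = 0.0380; adjusted p = 0.864 with an estimated correlation), among them Ly6c1, which passed adjusted over the list alone, Slco1c1 (0.43 ± 0.22) and Flt1 (0.40 ± 0.18). That call was lost without SPF replicate 1 (mean -0.06, adjusted p = 0.762), without conventional replicate 1 (mean 0.12, adjusted p = 0.0614) and without conventional replicate 2 (mean 0.17, adjusted p = 0.144), and under 3 of 10 other processing choices (highest adjusted p = 0.0831). Without SPF replicate 2 the mean was 0.36.

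Genes of tissues that border the cord differed between single arrays. Meningeal fibroblast genes fell as a set, with 16 of 16 lower and a mean of -0.88 (adjusted p = 1.37e-05; adjusted p = 0.864 with an estimated correlation), among them Slc13a4 (-1.83 ± 1.25), Igf2 (-1.44 ± 0.70) and Ogn (-1.28 ± 1.14). Relative to each gene's mean, the list stood at -0.52 and 1.39 on the SPF arrays and at 0.22 and -1.09 on the conventional arrays. Its mean was 0.08 without SPF replicate 2 (adjusted p = 0.599) and -0.22 without conventional replicate 2 (adjusted p = 0.282), but -1.83 without SPF replicate 1 and -1.53 without conventional replicate 1. Skeletal muscle genes fell with 10 of 11 lower and a mean of -0.94 (adjusted p = 1.33e-06; adjusted p = 0.814 with an estimated correlation), among them Tnnc2 (-1.51 ± 0.58, detected on 1 of 2 conventional arrays), Atp2a1 (-1.32 ± 0.61) and Myl1 (-1.14 ± 0.72). This list stood at 1.15 on SPF replicate 1 and between -0.76 and -0.18 on the other arrays, and without SPF replicate 1 its call was lost (mean -0.25, adjusted p = 0.0534), while without SPF replicate 2 the mean was -1.62.

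**Figure D2:**
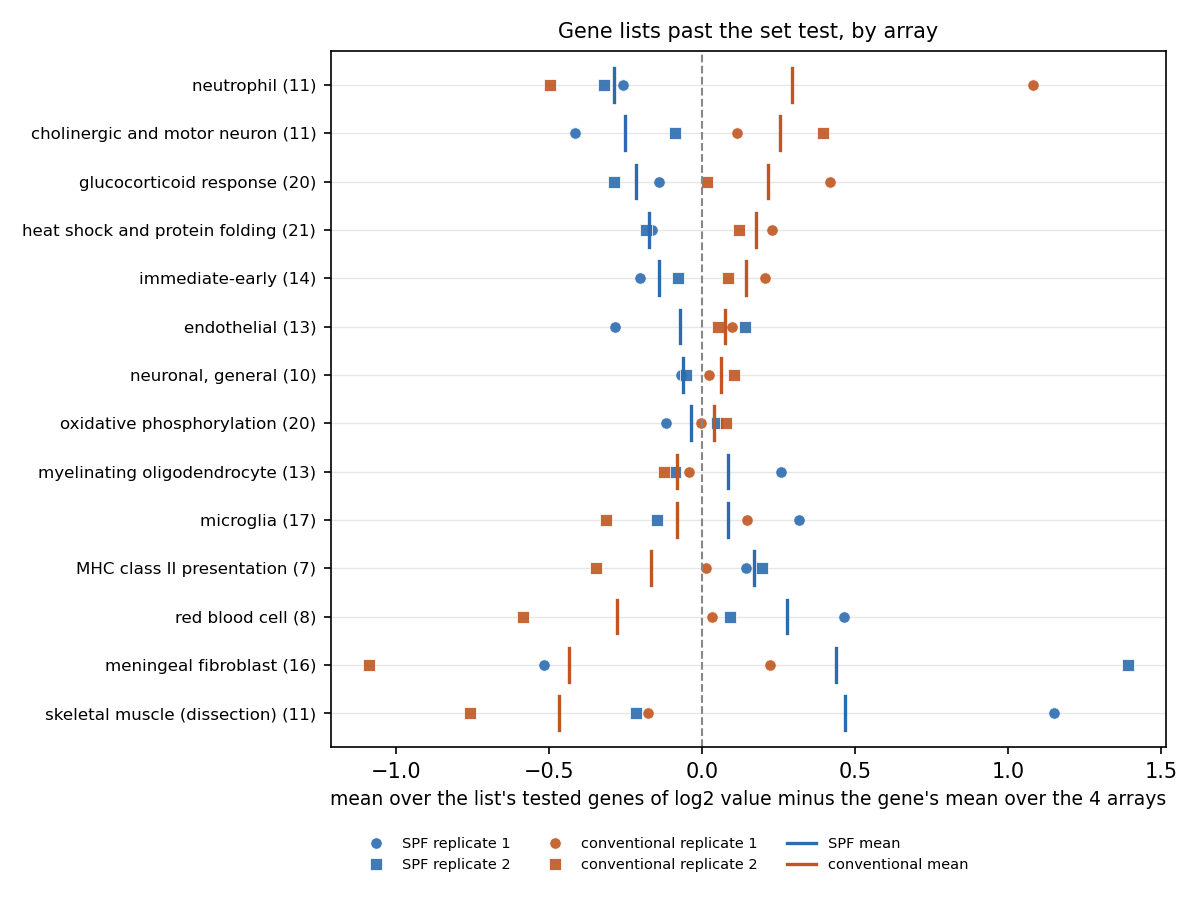
For each of the 14 lists past camera at the preset correlation (tested genes in brackets), the mean over its genes of the log2 value minus the gene's mean over the 4 arrays (x axis, log2 units); points are arrays, circles replicate 1 and squares replicate 2, and vertical bars are group means of 2 arrays. The heat shock, glucocorticoid, immediate-early, cholinergic and general neuronal lists have both conventional arrays above both SPF arrays, whereas the neutrophil list is high on conventional replicate 1 alone (1.08), the meningeal list on SPF replicate 2 (1.39) and the skeletal muscle list on SPF replicate 1 (1.15).

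The remaining lists did not pass: Schwann cell and nerve root (7 of 8 lower, adjusted p = 0.280), cholesterol synthesis (7 of 14 lower, adjusted p = 0.429), circadian clock (7 of 14 lower, adjusted p = 0.738), cell cycle (7 of 11 lower, adjusted p = 0.714), pericyte and smooth muscle (6 of 10 lower, adjusted p = 0.796), ependymal (4 of 8 lower, adjusted p = 0.800) and cytosolic ribosomal protein genes (9 of 19 lower, adjusted p = 0.813). Markers of dorsal root ganglion neurons (4 tested), T cells (4), B and plasma cells (2) and mast cells and basophils (3) were too few to test. Among clock genes, Dbp differed by -0.77 ± 0.24 and Nr1d1 by -0.76 ± 0.29. Dbp ranged from -1.14 without SPF replicate 2 to -0.40 without SPF replicate 1, and Nr1d1 from -1.16 without conventional replicate 2 to -0.36 without conventional replicate 1. Npas2, not above background on either SPF array, was at least 1.5-fold higher in conventional cord. It stood at 5.43 and 5.88 log2 units on conventional replicates 1 and 2, and the lowest values above background on the SPF arrays were 5.06 and 5.08. Schwann cell and nerve root genes had a mean of -0.43 without SPF replicate 1 and -0.37 without conventional replicate 1. In the same 2 fits the meningeal fibroblast list had means of -1.83 and -1.53. Cholesterol synthesis genes had a mean of -0.15 without SPF replicate 2.

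The 2 arrays of a group differed by more than the group means did. The median absolute log2 difference over genes was 0.199 between the SPF arrays, 0.195 between the conventional arrays and 0.127 between the group means. The last is 0.647 times the within-group difference (± 0.00794, SD over the 2 groups), where 0.707 is expected with no effect. This SD reflects only how alike the 2 within-group differences are, and says nothing about the precision of the ratio. The pairs closest to each other came from different groups: SPF and conventional replicate 2 differed by 0.151 and SPF and conventional replicate 1 by 0.179.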

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

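The 2 alternatives that leave genes out of the lists and the comparison of other splits were chosen after the result was seen; the rest were planned, and the slide as a block was not run because the files give no slide. The count of 0 genes in limma's test held under 10 other choices of background correction, normalization, filter, probe and variance model, and at an adjusted p under 0.1. It was 5 with the replicate number as a block (Opalin, Erdr1, Hba-a1, Hbb-bs and Hbb-bt, all lower) and 0 to 2 with 1 array left out, where the lone array of a group is assumed to vary like the others. Looser thresholds gave 443 (unadjusted p under 0.05), 60 (unadjusted p under 0.01 and at least 1.5-fold) and 35 (at least 2-fold, groups not overlapping, no test); the looser threshold itself is the reason. Of 14 lists past the threshold, 10 passed under all 10 choices and 5 without any 1 array (heat shock, cholinergic and motor neuron, glucocorticoid, immediate-early, red blood cell). The count was 9 to 18 with 1 array left out, 0 with an estimated correlation, 0 and 0 with fry, and 8 without each list's member of largest difference, where microglia, myelinating oligodendrocyte, general neuronal, endothelial, MHC class II and oxidative phosphorylation genes did not pass. The ratio of group to within-group difference moved from 0.647 to 0.690 without a filter on dim probes; the cause was not tested. Same-numbered arrays deviated together (correlation 0.198), and the labels do not say whether they share a batch or day. With 2 pairs this is too few to decide, so whether the numbers pair the samples stays unknown, and the 5 genes above hold only if they do. With the block 13 lists passed, and of the 14 the endothelial list was lost (adjusted p = 0.0978).

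The split of the arrays by replicate number gave 0 genes at an adjusted p under 0.05 but 2054 at an unadjusted p under 0.05. The groups gave 443 and the third split 288 at that unadjusted p. By chance 731.7 would be expected, and only the split by replicate number exceeded that count. The lowest adjusted p in limma's test was 0.0699 by replicate number, 0.476 for the groups and 0.234 in the third split. With 3 splits 1 must rank highest, so these counts do not decide whether the replicate numbers pair the samples. The groups gave 14 lists, 1 of 3 splits reached that number, and the highest other split gave 13; 3 splits are too few for a share under 0.05. Of the 14 lists, 4 passed in no other split: heat shock, immediate-early, general neuronal and MHC class II. The other lists also passed in a split that ignores housing, 8 of the 14 by replicate number and 4 in the third split. Among them were glucocorticoid (camera at the preset correlation, adjusted p = 0.00772), cholinergic (0.0293) and red blood cell genes (0.0333) by replicate number. Meningeal genes had an adjusted p of 8.97e-34 in the third split, against 1.37e-05 for the groups. Detection limits the dim genes, since 45.3%, 44.9%, 45.7% and 46.3% of probes were above background.

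These turned direction with some array left out (range of the mean or log2 difference over the 4 fits); for lists the direction is that of the test. In some, either of 2 arrays turned it when left out, and the cause was not tested. Lists: pan-reactive astrocyte -0.31 to 0.55, A1-type -0.45 to 0.15, homeostatic astrocyte -0.0716 to 0.0601, microglia -0.40 to 0.0627, myelinating oligodendrocyte -0.34 to 0.00562, oligodendrocyte precursor -0.13 to 0.18, itch and pain -0.17 to 0.35, excitatory neuron -0.24 to 0.075, Schwann cell -0.43 to 0.10, endothelial -0.0649 to 0.36, pericyte -0.0755 to 0.0843, meningeal -1.83 to 0.0815, ependymal -0.14 to 0.0806, neutrophil -0.21 to 1.37, type 2 cytokine -0.0963 to 0.0341, interferon -0.26 to 0.0431, complement -0.73 to 0.0907, circadian clock -0.18 to 0.0711, cholesterol synthesis -0.15 to 0.0749, oxidative phosphorylation -0.0111 to 0.16, ribosomal protein -0.0411 to 0.075 and cell cycle -0.12 to 0.0491. Genes: Cp -1.57 to 0.24, Aspg -1.29 to 0.22, Aspa -0.50 to 0.10, Mog -0.52 to 0.14, Gal -0.0493 to 1.53, Pdyn -0.11 to 1.29, Ogn -2.89 to 0.35, S100a8 -0.33 to 1.87, S100a9 -0.61 to 2.05, Gfap -0.26 to 0.59, Stat3 -0.11 to 0.0746, Grp -0.29 to 0.88, Grpr -0.45 to 0.0205, Tac2 -0.75 to 0.17, Sst -0.51 to 0.23, Th -0.36 to 0.74 and Hspa1b -0.10 to 0.19. Among the genes followed, those that kept direction but moved by over 1.5 times were, beside those whose value without an array is given elsewhere, Tyrobp (-1.15 to -0.22), Trem2 (-0.83 to -0.0483), Gpr34 (-0.47 to -0.19), H2-Eb1 (-0.97 to -0.15), Gap43 (0.12 to 0.42), Isl1 (0.26 to 1.15), Prph (0.34 to 0.81), Ret (0.27 to 0.70), Ndufa2 (0.12 to 0.24), Map2 (0.0744 to 0.23), Atp5j (0.087 to 0.30), Egr3 (0.40 to 1.07), Flt1 (0.16 to 0.64), Slc13a4 (-3.60 to -0.0591), Igf2 (-2.50 to -0.38), Tnnc2 (-2.40 to -0.62), Atp2a1 (-2.24 to -0.41) and Myl1 (-2.28 to -0.00552). Among the other reversals, the test's direction turned while the mean kept its sign for homeostatic astrocyte, circadian clock, ribosomal protein and type 2 cytokine genes; the cause was not tested. Without genes of several lists, pan-reactive astrocyte genes had a mean of -0.0881 and pericyte genes -0.0487. Without the largest member, homeostatic astrocyte genes had -0.0331, inhibitory neuron genes -0.0159, circadian clock genes -0.00123 and ribosomal protein genes 0.00836. Probes with a detection p under 0.01 on all 4 arrays gave pericyte genes -0.047, no filter gave type 2 cytokine genes -0.0447, cyclic loess gave ribosomal protein genes 0.00234, and the mean of its probes gave Stat3 0.195. Mean, median and test differed in sign for oligodendrocyte precursor (mean 0.02, median -0.03, test lower), homeostatic astrocyte (mean -0.01, median 0.02, test higher) and pericyte genes (mean 0.00441, median -0.00576, test higher).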

Other observations

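The tests of explanations here, and the choice by hand of the 4 genes named next, were made after the result was seen. In each of the 4 both conventional arrays lay above both SPF arrays. That held for 15.6% of all features, where chance gives 16.7%, so it does not set these genes apart. None of the 4 passed limma's test over all genes: Avp, which encodes vasopressin (at least 1.85-fold higher, not above background on either SPF array), Vip, which encodes vasoactive intestinal peptide (log2 difference 1.35 ± 0.34, standard error, detected on 1 of 2 SPF arrays), Bdnf, which encodes brain-derived neurotrophic factor (0.94 ± 0.28; other probes as low as 0.32), and Lrg1, a secreted leucine-rich glycoprotein gene (1.98 ± 0.57). Lrg1 stood at 5.55 and 7.24 log2 units on the SPF arrays and at 8.92 and 7.83 on the conventional arrays. Avp stood at 6.61 and 5.30 log2 units on conventional replicates 1 and 2. The lowest values above background on the SPF arrays were 5.06 and 5.08, so its bound rests mostly on conventional replicate 1. With 1 array left out, the log2 difference ranged from 0.55 to 1.33 for Bdnf (lowest without conventional replicate 1, highest without conventional replicate 2). It ranged from 0.87 to 1.83 for Vip and 1.13 to 2.83 for Lrg1 (lowest without SPF replicate 1, highest without SPF replicate 2). These genes form no fixed list: the fixed list of itch and pain peptides and receptors did not pass (14 of 23 higher, adjusted p = 0.374). Its peptide genes Ucn3 (-0.57 ± 0.30, detected on 1 of 2 conventional arrays), Nts (-0.36 ± 0.30), Tac2 (-0.29 ± 0.37) and Sst (-0.14 ± 0.25) had lower means in conventional cord. With 1 array left out Ucn3 ranged from -0.90 to -0.24 and Nts from -0.68 to -0.0363 (lowest without conventional replicate 1, highest without conventional replicate 2). Tac2 turned to 0.17 and Sst to 0.23 without SPF replicate 1, and to 0.17 and 0.0751 without conventional replicate 2.

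Meningeal fibroblast and skeletal muscle genes were lower in conventional cord. Normalization between arrays as the whole cause is argued against. Both lists kept direction and call under 4 other choices of background correction and normalization (camera at the preset correlation, highest adjusted p = 3.73e-05 for meningeal and 6.71e-06 for muscle genes). Neither kept its call with the correlation estimated (adjusted p = 0.864 with an estimated correlation for meningeal and adjusted p = 0.814 with an estimated correlation for muscle genes). That test called 0% of lists shifted by 0.5 log2 units in the simulation. Shifts as large as those of these lists (means -0.88 and -0.94) were not simulated, so it decides nothing here. With fry for a shift in 1 direction the adjusted p was 0.923 for meningeal and 0.891 for muscle genes. Tissue carried over in dissection, in amounts that differ from sample to sample, is a candidate explanation: the gap between the 2 SPF arrays was 2.18 times the gap between the groups for meningeal genes and 1.46 times for muscle genes. On SPF 1, SPF 2, conventional 1 and conventional 2, Igf2 of the meningeal list stood at 11.84, 13.97, 12.20 and 10.73 and Myl1 of the muscle list at 9.95, 7.67, 8.31 and 7.01. Pvalb, which spinal neurons also express, was the muscle list's 1 member that was higher (0.19 ± 0.29), and an effect of housing on these tissues stays open and untested.

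Heat shock, glucocorticoid and immediate-early genes were higher in conventional cord. A single array as the whole cause is argued against for heat shock and immediate-early genes. Their lowest means without any 1 array were 0.295 and 0.223, against 0.347 and 0.286. The glucocorticoid mean was 0.23 without conventional replicate 1, against 0.43, so a large share from that array stays open. Direction could not turn, since both conventional arrays stood above both SPF arrays in each list mean. Each list kept its camera call at the preset correlation without any 1 array (highest adjusted p = 0.00622). That call decides little, since the estimated correlations were above the preset one. Normalization is argued against (highest adjusted p = 9.43e-05 over 4 other choices), although no list kept its call with the correlation estimated (adjusted p = 0.814 with an estimated correlation for each). Time of day or handling at collection cannot be told apart from housing here: the circadian clock list did not pass (adjusted p = 0.738; with fry for change in either direction, adjusted p = 0.901), but its 14 genes have intervals reaching from -1.44 to 1.19, and the labels give no collection times. A shift in phase moves clock genes in opposite directions, which a test of 1 direction misses. Dbp (-0.77 ± 0.24, and -0.40 without SPF replicate 1) and Nr1d1 (-0.76 ± 0.29, and -0.36 without conventional replicate 1) were lower. Npas2 was at least 1.5-fold higher, at 5.43 and 5.88 log2 units on conventional replicates 1 and 2. None of these genes passed limma's test. An effect of the housing or of the dermatitis stays open and untested.

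Lcn2 was higher on both conventional arrays, by 3.17 on replicate 1 and 1.43 on replicate 2 over the SPF mean. On replicate 1 the other 10 neutrophil genes were all above the SPF mean, by a median of 1.20 (S100a8 at 10.88 against 9.18 and 8.84 on the SPF arrays), so neutrophils in the tissue or its blood may contribute there. Relative to each gene's mean, red blood cell genes stood at 0.03 on that array, against 0.46 and 0.09 on the SPF arrays. A larger amount of blood is thus not shown there. On replicate 2 the median of those genes was -0.452 and 2 of 10 were above, which argues against neutrophils as the source on that array. Reactive astrocytes, which can make Lcn2, stay open. The other 13 pan-reactive genes had a mean difference of -0.047 with 7 higher, but this mean pools arrays that moved in opposite directions. Relative to each gene's mean, the list with Lcn2 stood at 0.49 on conventional replicate 1 and -0.37 on replicate 2. It stood at 0.04 and -0.16 on the SPF arrays. Lcn2 itself raises both conventional values. On replicate 2 the list with Lcn2 was -0.31 against the SPF mean, so its other members as a set did not rise there with Lcn2. The neutrophil genes did not rise on that array either. By array the list thus moved as the neutrophil genes did, and the pooled mean cannot decide. For either source the values on replicate 2 rest on 1 array.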
